A study of Zea mays with 20 samples.

How the data were processed

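Total RNA from the ear internode of field-grown, irrigated maize was measured on an Affymetrix maize oligonucleotide array in 5 recombinant inbred lines at 2 harvest stages. There were 2 arrays for each of the 10 combinations of line and stage, 20 arrays in all. The deposited values are log2 expression per probe set, which the authors made with GCRMA, a method that corrects for background, normalizes between arrays and summarises the probes of a probe set. No GCRMA version was given. The values ran from 1.37 to 15.2, and no further transformation was applied to them. The number of arrays limits the precision of every value.

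The table holds 17555 maize probe sets and 179 control probe sets, and the controls were left out of all tests. A probe set was tested when its log2 value was above 5 in at least 2 of the 20 arrays, which left 11033 and set aside 6522. Values were fitted in limma 3.58.1 under R 4.3.3 with a mean for each of the 10 groups and no replicate block, since replicate numbers did not pair the arrays. Over the 45 pairs of groups, the correlation between differences of replicate 2 and replicate 1 ran from -0.436 to 0.512, and 16 pairs were above 0.1. All groups shared a spread with 10 residual degrees of freedom, moderated by eBayes with 2.37 prior degrees of freedom. It is the spread between arrays of the same line and stage, so the SE and p of this fit do not measure the spread between lines. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all tested probe sets, and a probe set past it is called. Stage and line contrasts weighted lines and stages equally. Differences are log2 values with the standard error (SE) of the fit, and group means carry the standard deviation (SD) over arrays, which includes differences between lines or stages within the group. Where leaving out an array left a group with 1 array, that array was assumed to vary like those of the other groups.

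The platform annotation available lists a gene for only 1453 of the maize probe sets and none for the other 16102. Of the listed probe sets, 961 passed the filter, and they stood for 808 genes. The annotation holds no gene descriptions and nearly all its symbols are placeholders, so synonyms served as names. Chromosomes were taken from the RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0. Positions are given by chromosome, and the order of genes on chromosome 4 was taken from the gene starts in the same table. The bins were not placed on the assembly, so calls were tested by whole chromosome and not by bin. The 35 gene lists, the comparisons, the tests, the filter and the rule for named genes were fixed before the data were examined. Matching by synonym brought some unintended members into the lists, which are named where they matter.

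The named genes of the stage and locus comparisons were the 6 largest rises and 6 largest falls among called probe sets with 1 named gene that changed the same way in every line or in every pair of lines and stages. To these were added up to 3 called members of each gene list described, and the measured genes of the phenylpropanoid entry and of the monolignol steps whether called or not. For the interactions, the line differences and the differences within a class, the 3 called named genes with the smallest p were taken. The list members expB6, ss2, lg3, rbcs1, Cab-m7, RPL10 and krp1, and rpl29 in the stage comparison, were named outside this rule after their values were seen. In the stage comparison tub5, tub6, rps6 and dhn2 are given at their brightest probe set, not at the one with the largest change. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, 1 probe set per gene, and adjusted over the 14 lists tested. The test was repeated with an estimated correlation and with fry. Members of every list were also adjusted over the list alone. Enrichment of calls on a chromosome was tested with Fisher's exact test, two-sided, against all tested probe sets with 1 chromosome.

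The fit was tested on simulated data with 200 changed probe sets. Of the changes of 1 on the log2 scale, 88% were called for the stage effect, 76% for the bin 6.06 comparison, 68% for the bin 9.02 comparison and 42% for the stage effect within RIL99. False calls made up 3.92% to 5.46% of calls. The simulation gave all groups the same spread for a probe set. In the data the SD between replicates ran from 0.18 (RIL39 at emerging tassel) to 0.61 (RIL118 at emerging tassel). Far more than 200 probe sets were also called in these comparisons of the data. The simulated shares may therefore not hold for the measured values. A simulated list with a shift was called, and 0 of 100 lists without a shift were called by camera after adjustment, 3 of them having an unadjusted p under the threshold. The simulated probe sets varied independently, so this does not test the preset correlation on lists whose genes vary together. In the measured lists the estimated correlation was 0.878 for secondary-wall cellulose and 0.275 for tubulins.

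The alternatives tried were a replicate block, no filter, a stricter filter, quantile normalization, centring of each array on its median, a trended and robust eBayes, a fit of only the groups compared, the line as a random block, the RNA amount as a covariate, 1 probe set per gene, and leaving out each array in turn. A covariate for RNA quality, a fit without RIL118, a fit without the 2 RIL39 arrays of lowest 5′ signal, and lists without unintended members were added after the data were seen. RNA quality was read from the 5′ minus 3′ signal of the maize control transcripts on each array. No group held enough arrays for an outlier test.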

Results

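Gene expression was measured in the ear internode, the stem segment that bears the ear, of 5 maize recombinant inbred lines from the cross of F288 and F271. The lines were chosen by their alleles at 4 loci for lignin content and cell wall degradability. RIL99 and RIL54 carry the favorable allele at all 4, RIL39 and RIL71 the unfavorable allele at bin 6.06, and RIL118 the unfavorable allele at bin 9.02. Each line was sampled at emerging tassel and at early silking, with 2 arrays per line and stage. Between 57.2% and 58.0% of the maize probe sets had a log2 value above 5 on each array. Replicate arrays correlated at 0.934 (RIL118 at emerging tassel) to 0.994 (RIL39 at emerging tassel). The RIL118 tassel arrays resembled each other less than an array of another group, with a highest correlation outside the group of 0.939. The first principal component carried 35.9% of the variance and separated the stages. The RNA amounts in the labels were 113.41 to 417.25 ng at emerging tassel and 53.001 to 201.72 ng at early silking, so amount and stage overlapped only in part.

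The stage comparison asked how the internode changed between emerging tassel and early silking. The 6 largest falls among the named genes included an invertase and an expansin. ivr2, a soluble acid invertase (gene 542324, chromosome 5), fell from 12.23 ± 0.75 to 5.32 ± 2.64 (SD, n = 10 each), a log2 change of -6.91 (SE 0.18) with adjusted p = 1.38e-10. The silking arrays of RIL99 and RIL54 lay at the floor of the array values for ivr2 (1.88 to 2.68). The expansin expA4 (gene 541906) fell from 7.69 ± 1.47 to 2.56 ± 0.81, a change of -5.13 (SE 0.40, adjusted p = 4.88e-07). The other largest falls were gar2 (gene 541620, chromosome 10) at -7.36 (SE 0.56), gst12, a glutathione transferase (gene 541830, chromosome 1), at -5.81 (SE 0.68), prp2, a pathogenesis-related protein (gene 542195, chromosome 2), at -5.55 (SE 0.54), and LPE1, a leaf permease (gene 542332, chromosome 1), at -4.92 (SE 0.40). At silking, gst12 (1.95 ± 0.04) and LPE1 (2.17 ± 0.22) also lay at the floor, and expA4 lay near it, which limits the size of change that can be read. The largest rise was that of ys1, the transporter of iron bound to phytosiderophores (gene 541800, chromosome 5), from 4.01 ± 1.18 to 6.86 ± 0.46, a change of 2.84 (SE 0.28, adjusted p = 2.74e-06). myb42, a MYB factor known to repress phenylpropanoid genes (gene 100101513, chromosome 4), rose by 2.28 (SE 0.16, adjusted p = 2.27e-07). thi1 of thiamine synthesis (gene 542714, chromosome 8) rose from 9.07 ± 1.04 to 11.27 ± 0.34. The tonoplast aquaporin tip4a (gene 541897, chromosome 6) rose by 2.16 (SE 0.28), sps1, a sucrose phosphate synthase (gene 542711, chromosome 8), by 2.06 (SE 0.30), and the response regulator RR7 (gene 541633, chromosome 4) by 2.01 (SE 0.25). Each of these 12 genes changed the same way in 5 of 5 lines, as the rule that chose them required. The SE and p of the stage changes leave out how the change varied between lines. For ivr2 it ran from -10.79 in RIL99 to -4.06 in RIL118. In the whole table, 7466 of 11033 probe sets were called, 4508 higher and 2958 lower at silking, and 5688 of them changed the same way in all 5 lines. Of those that changed at least 2-fold, 813 were higher and 1200 lower. The median change of all tested probe sets was 0.12.

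Most measured members of the expansin, secondary-wall cellulose and tubulin lists fell at silking, though none of the 3 list calls held with an estimated correlation. All 8 measured expansins fell (8 adjusted over the list alone), among them expB4 at -3.97 (SE 0.31) and expB6 at -2.83 (SE 0.22). All 5 measured genes of secondary-wall cellulose synthesis fell (5 adjusted over the list alone), with bk2, a COBRA-like protein of stem strength, at -2.24 (SE 0.24), cesa11 at -1.98 (SE 0.22) and cesa10 at -1.83 (SE 0.21). Of 12 tubulins, 10 fell and 2 were not called (11 adjusted over the list alone, and 11 after centring), with TUBB2 at -1.62 (SE 0.09), tub5 at -1.54 (SE 0.15) and tub6 at -1.34 (SE 0.09). These are the brightest probe sets of each gene, and dimmer ones fell further, to -3.11 (SE 0.62) for tub5 and -3.08 (SE 0.23) for tub6. The preset test called tubulins (adjusted p = 1.15e-05), expansins (0.000153) and secondary-wall cellulose (0.00258). The values were adjusted p = 0.278 for tubulins and expansins and adjusted p = 0.59 for cellulose, each with an estimated correlation. Of 6 genes of primary-wall cellulose synthesis, 4 fell and 1 rose (4 and 1 adjusted over the list alone; list adjusted p = 0.132), with cesa8 at -1.71, cesa2 at -1.06 and cesa6 at -0.72. Few lignin genes could be named from the annotation. All 3 named monolignol genes fell (3 adjusted over the list alone): ccr2, a cinnamoyl-CoA reductase, from 5.31 to 2.85 at -2.46 (SE 0.47, adjusted p = 0.0005), BM1, a cinnamyl alcohol dehydrogenase, at -0.55 (SE 0.06, adjusted p = 7.66e-06), and cncr1, a second cinnamoyl-CoA reductase, at -0.24 (SE 0.10, adjusted p = 0.038), lower in 4 of 5 lines. The cncr1 call was lost after quantile normalization (adjusted p = 0.0851), with the RNA covariate (adjusted p = 0.0819) and without the 2 RIL39 arrays of lowest 5′ signal (0.0766), and it held only when the array left out was RIL71 tassel replicate 1, RIL54 tassel replicate 2, RIL39 tassel replicate 2, RIL39 silking replicate 1, RIL118 silking replicate 1 or RIL54 silking replicate 2. Of the phenylpropanoid entry genes, the 4-coumarate ligase LOC542166 fell (-1.15, SE 0.18, adjusted p = 0.000109), while pal3, a phenylalanine ammonia lyase, was at -0.13 (SE 0.07, adjusted p = 0.117), a value that passed after centring; 1 of 2 passed adjusted over the list alone. The laccase LAC1 rose by 1.24 (SE 0.20), and both measured class III peroxidases fell, pox2 at -1.21 (SE 0.21) and PER42 at -1.06 (SE 0.18).

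**Figure D1:**
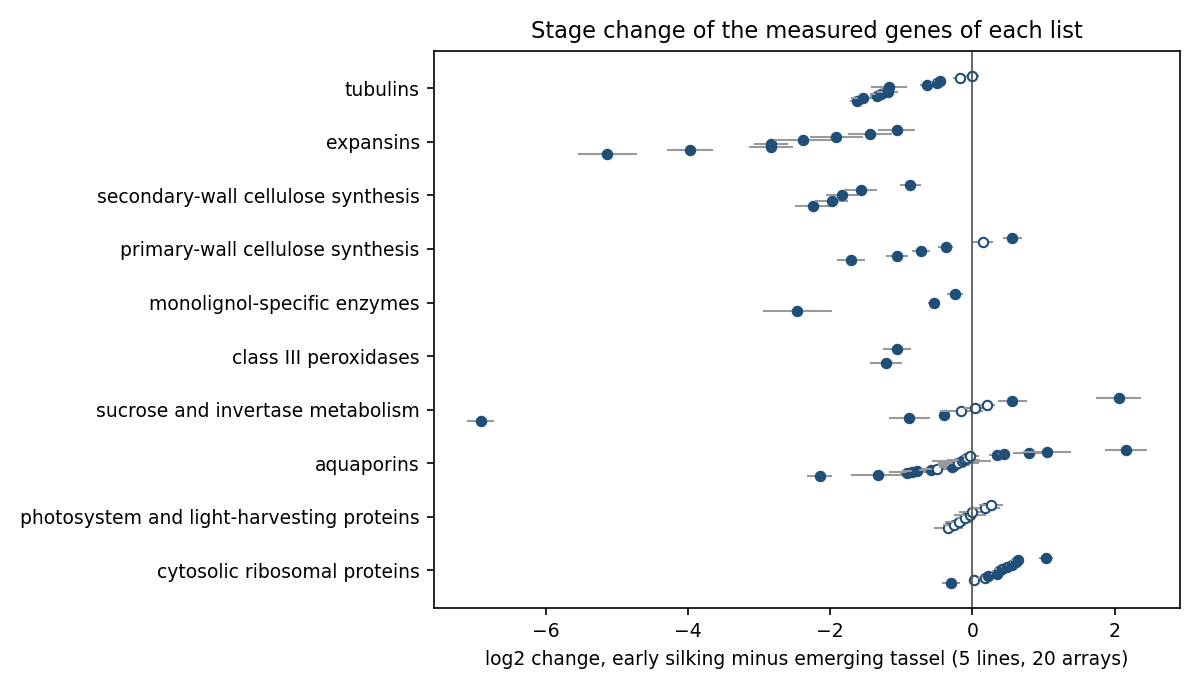
Log2 change from emerging tassel to early silking for the measured genes of 10 gene lists, with bars of 1 SE of the fit; filled points passed adjusted p 0.05 and open points did not. All 8 expansins and all 5 genes of secondary-wall cellulose synthesis lie below 0, and 9 of 12 ribosomal proteins are called above 0.

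Cytosolic ribosomal proteins moved the other way. Of 12 genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone), with RPL19 at 1.04 (SE 0.08), rps6 at 0.64 and rps27 at 0.61, against rpl29 at -0.30. The rpl29 call was lost with the RNA covariate (adjusted p = 0.16), with the line as a random block (0.0752), without the 2 RIL39 arrays of lowest 5′ signal (0.0874), and without any 1 of RIL39 tassel replicate 1, RIL99, RIL54 and RIL71 tassel replicate 2, RIL71 and RIL118 silking replicate 1, and RIL99, RIL54 and RIL39 silking replicate 2 (0.0529 to 0.0657). The list's adjusted p was 0.0449, and adjusted p = 0.59 with an estimated correlation. In starch synthesis, sbe1, a branching enzyme, rose by 1.24 (SE 0.13), bt2, an ADP-glucose pyrophosphorylase subunit, by 0.80 (SE 0.12) and ss1, a starch synthase, by 0.58 (SE 0.11). The list counted 3 rises and 1 fall of 5, the fall being ss2, which is also named sus1, a sucrose synthase (-0.41). In sucrose metabolism, 2 genes rose and 3 fell of 8 (3 and 3 adjusted over the list alone), with ivr2 and sps1 as above and the wall invertase incw1 at -0.89 (SE 0.27). Aquaporins split, with 5 of 22 higher and 8 lower (10 lower after centring); tip1 fell (-2.15, SE 0.16) and so did nip1a (-1.33, SE 0.36), a call lost with the RNA covariate. Both measured dehydrins fell, dhn1 at -3.17 (SE 0.63) and dhn2 at -0.99 (SE 0.16; -0.80 to -1.46 at its other probe sets), and so did the lipid transfer protein plt2 (-2.44, SE 0.41). Of 8 heat shock proteins 2 rose and 3 fell, and of 10 senescence and nitrogen genes 3 rose and 1 fell. The preset test gave adjusted p = 0.477 for starch, 0.423 for sucrose and for heat shock, 0.132 for aquaporins and 0.693 for senescence. None of the 8 photosystem genes was called at the probe set that stood for the gene (limma; 0 at an unadjusted p under 0.05), and the list's adjusted p was 0.505. Of the list's 10 probe sets 2 were lower, both of lhcb6, with 1 of them at -0.76 (SE 0.22, adjusted p = 0.00763). Markers of other tissues moved as well. Among meristem regulators fea2 (1.61, SE 0.19), kn1 (0.58) and knox7 (0.43) rose and lg3 fell (-0.30), a call lost with the line as a random block (adjusted p = 0.0722) and without the 2 RIL39 arrays (0.0717). The direction held in 4 of 5 lines for pox2, sbe1, nip1a, kn1 and knox7, and in 3 of 5 for lg3. Of 3 leaf epidermis genes 2 fell, fae1 (-2.82, SE 0.24) and ocl3 (-0.70, SE 0.25). The ocl3 call was lost with the RNA covariate (adjusted p = 0.218) and without any 1 of RIL99 or RIL118 tassel replicate 1, RIL54 tassel replicate 2, or RIL71 or RIL118 silking replicate 2 (0.0541 to 0.0577). Of 3 genes matched as kernel proteins 2 fell, emp2 (-0.48), a heat shock factor binding protein, and gz27, a zein (-0.83, SE 0.30; lower in 3 of 5 lines). The gz27 call was lost without a filter (adjusted p = 0.0524), with the RNA covariate (0.42), without RIL118 (0.141), and without any 1 of RIL99 or RIL118 tassel replicate 1, RIL54 or RIL71 tassel replicate 2, RIL39 silking replicate 1 or RIL54 silking replicate 2 (0.0515 to 0.0576). The 5′ minus 3′ signal of the control transcripts differed by -0.13 between stages (permutation p = 0.71, two-sided). With the replicate block the stage count was 7384.

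To see whether the stage change was shared by the lines, it was tested in each line and then as an interaction. The invertase ivr2 changed by -10.79 in RIL99 and -10.28 in RIL54, but by -4.10 in RIL39, -5.32 in RIL71 and -4.06 in RIL118 (SE 0.40 in each line; adjusted p = 1.42e-05 for the interaction of stage and line). At silking ivr2 was at the floor in RIL99 and RIL54 (1.88 to 2.68 on their 4 arrays), which limits the size of their falls and of the differences from them that can be read. The difference was 5.82 (SE 0.40, adjusted p = 5.67e-06) between the bin 6.06 class and the favorable lines, and 6.48 (SE 0.48, adjusted p = 5.68e-05) between RIL118 and the favorable lines. hsp22, a small heat shock protein (chromosome 4), changed by -8.64 in RIL99, -4.82 in RIL54 and -5.74 in RIL71, whereas its values in RIL39 (1.03) and RIL118 (0.96) had the opposite sign (SE 0.63; adjusted p = 0.000112). Its difference was 4.37 (SE 0.63, adjusted p = 0.00461) for the bin 6.06 class, a call lost without the 2 RIL39 arrays of lowest 5′ signal, and 7.69 (SE 0.77, adjusted p = 0.000533) for RIL118. At silking hsp22 was at 3.36 and 3.37 in RIL99 and 3.44 and 3.43 in RIL71. These values lie under the filter value of 5, which limits the size of its changes that can be read. b3gat3 fell in RIL99 (-4.89, SE 0.16) and stayed at 2.27 to 2.32 in the other lines, so its interactions (2.46 and 2.47; adjusted p = 2.88e-07 among lines, 5.67e-06 for the bin 6.06 class and 5.74e-05 for RIL118) rest on RIL99. Within lines, 4983 probe sets were called in RIL99, 4074 in RIL54, 3616 in RIL71, 2993 in RIL39 and 1288 in RIL118. The interaction was called for 679 probe sets among the 5 lines, for 89 between the bin 6.06 class and the favorable lines (39 higher, 50 lower), and for 865 between RIL118 and the favorable lines (364 higher, 501 lower). With the replicate block the within-line counts were 4886, 3917, 3440, 2823 and 1133 in that order, and the interactions 567, 86 and 630.

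**Figure D2:**
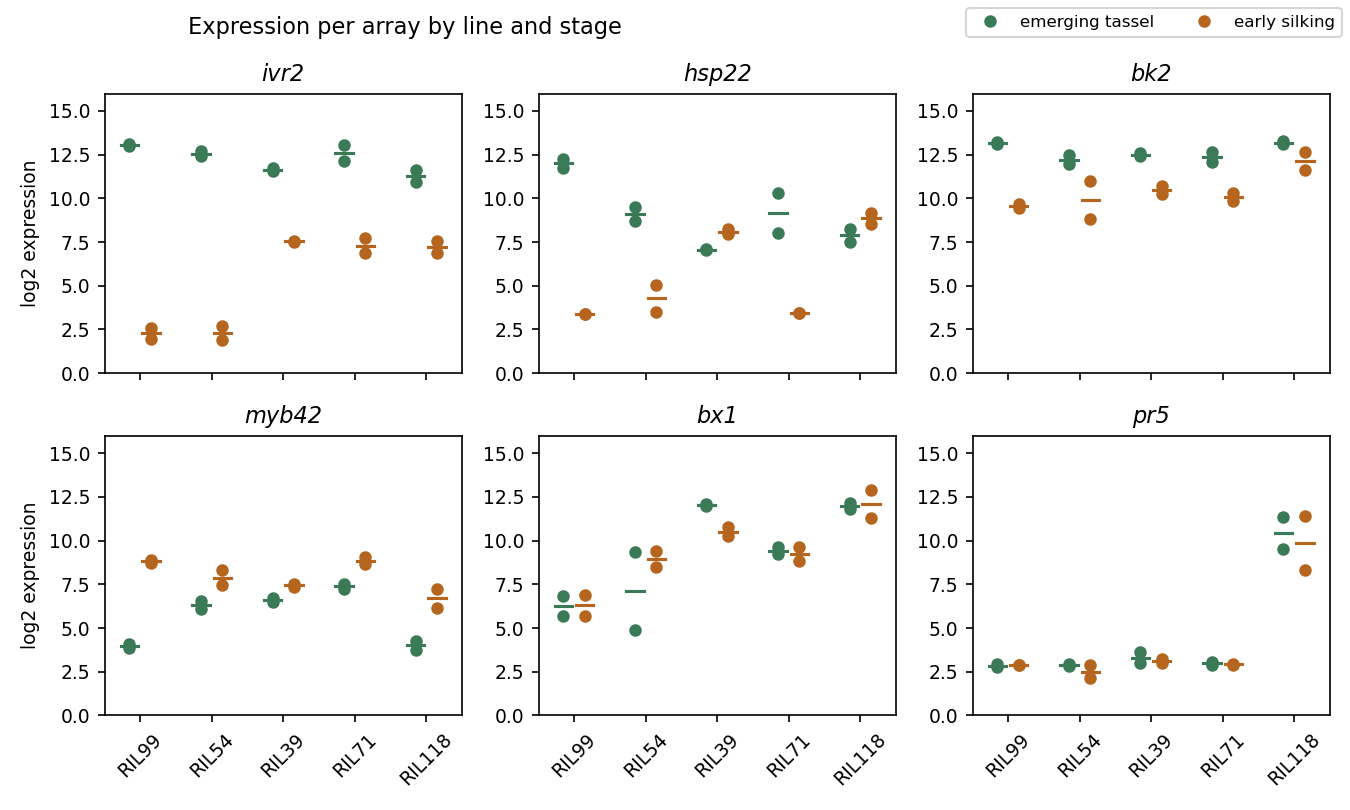
Log2 expression of ivr2, hsp22, bk2, myb42, bx1 and pr5 on each of the 20 arrays by line and stage; dots are arrays and bars the mean of the 2 arrays of a group. ivr2 is lowest at silking in RIL99 and RIL54, and pr5 is high only in RIL118, where its mean is 10.14.

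The counts by line changed when single arrays were left out. Leaving out 1 of the 2 arrays of a group raises the standard error of its contrasts, so part of the falls can come from lost precision. Without RIL99 tassel replicate 1, the stage effect in RIL99 was called for 3239 probe sets. The stage effect in RIL54 gave 2287 without its tassel replicate 2 and 2043 without its silking replicate 1. The stage effect in RIL39 gave 1274 and 1233 without tassel replicates 1 and 2, and 1609 and 1586 without silking replicates 1 and 2. The stage effect in RIL71 gave 1893 without tassel replicate 1 and 1566 without silking replicate 2. The stage effect in RIL118 gave 562 without tassel replicate 1, 764 without silking replicate 1 and 180 without silking replicate 2. The stage by line interaction gave 1195 without RIL54 tassel replicate 1; 398, 341 and 320 without RIL99 tassel replicate 1, silking replicate 1 and silking replicate 2; and 356, 334, 403 and 424 without RIL39 tassel replicates 1 and 2 and silking replicates 1 and 2. The bin 6.06 class by stage interaction rose to 206 without RIL54 tassel replicate 1, 152 without RIL71 tassel replicate 2, 150 without RIL54 silking replicate 2, and 135 without either RIL118 tassel array, and fell to 59 and 55 without RIL39 tassel replicates 1 and 2. The bin 9.02 line by stage interaction was 1585 without RIL54 tassel replicate 1. It was 573 without RIL54 tassel replicate 2 and 419 without RIL54 silking replicate 1. Without RIL99 tassel replicates 1 and 2 it was 414 and 574, and without RIL99 silking replicates 1 and 2 it was 399 and 372. Without either RIL39 tassel array it was 471. It was 533 without RIL118 tassel replicate 1, 172 without RIL118 silking replicate 1 and 472 without RIL118 silking replicate 2.

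The bin 6.06 comparison set RIL39 and RIL71 against RIL99 and RIL54 over both stages, to find genes that differ with the unfavorable allele. rip2, a ribosome-inactivating protein (gene 541814, chromosome 7), was at 6.49 ± 1.51 in the bin 6.06 class and at the floor of the array (2.16 ± 0.02) in the favorable lines (SD, n = 8 each), a difference of 4.33 (SE 0.29), adjusted p = 2.18e-07. bx1, which makes the first step of benzoxazinoid synthesis (gene 542117, chromosome 4), was higher by 3.14 (SE 0.53, adjusted p = 0.00102), and bx6 of the same pathway (gene 541977, chromosome 4) by 2.66 (SE 0.25, adjusted p = 7.52e-06). The ferredoxin fdx2 (gene 541619, chromosome 6) was higher by 2.62 (SE 0.32), the lipoxygenase lox3 (gene 542495, chromosome 1) by 1.91 (SE 0.27) and pdrp1, the regulator of pyruvate phosphate dikinase (gene 732785, chromosome 2), by 1.31 (SE 0.33). Lower in the class were piip2 (gene 541647, chromosome 5; -2.34, SE 0.51), acco20, an ACC oxidase of ethylene synthesis (gene 542137, chromosome 4; -1.77, SE 0.27), the alternative oxidase aox1 (gene 542073, chromosome 5; -1.63, SE 0.12), HIT2 (gene 541689, chromosome 4; -1.57, SE 0.32), GP (gene 541968, chromosome 4; -1.29, SE 0.17) and hac106 (gene 542083, chromosome 7; -1.27, SE 0.13). Each differed the same way in 8 of 8 pairs of lines at a stage, as the rule that chose them required. The aox1 difference rests on RIL54, where aox1 (gene 542073) was at 5.92 at tassel and 6.11 at silking, against means of 2.65 to 3.09 in the other lines. In all, 2023 probe sets were called, 1093 higher and 930 lower, of which 831 differed the same way in all 8 pairs. The 2 lines of the class differed unequally from RIL99 and RIL54: RIL39 alone gave 3043 calls against them and RIL71 alone 1225. The spread behind these calls is that between arrays of a line. With the line as a random block the count was 174 (1132 at an unadjusted p under 0.05), and of the 12 genes above rip2, bx6, fdx2 and GP passed (adjusted p = 1.47e-05, 0.0248, 0.0142 and 0.0125) and 8 did not. That block used 1 correlation within lines, 0.303, for all probe sets. For a gene whose lines differ more than this, it is not a test against the spread between its own lines.

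Of the monolignol and phenylpropanoid entry genes that the annotation names, none passed for the bin 6.06 class. The monolignol genes ccr2 (-0.49, SE 0.52, adjusted p = 0.566), cncr1 (-0.24, SE 0.11, adjusted p = 0.136) and BM1 (-0.19, SE 0.07, adjusted p = 0.0702) did not pass (limma; 2 of 3 at an unadjusted p under 0.05, and 1 of 3 lower adjusted over the list alone), nor did LOC542166 (-0.54, SE 0.20, adjusted p = 0.0825) and pal3 (-0.04, SE 0.08, adjusted p = 0.767; 1 of 2 at an unadjusted p under 0.05, and 1 of 2 lower adjusted over the list alone). Both peroxidases were lower, PER42 at -1.51 (SE 0.21, adjusted p = 0.000205) and pox2 at -1.08 (SE 0.24, adjusted p = 0.0064), and myb42 was higher by 0.83 (SE 0.17, adjusted p = 0.00522), though in RIL39 at silking (7.44) it was below both favorable lines (7.88 and 8.82). The xyloglucan endotransglucosylase xet1 was lower (-0.83, SE 0.15), and of 8 expansins only EXPA5 was called, lower at -1.66 (SE 0.40). None of the 5 genes of secondary-wall cellulose synthesis was called (limma; 0 at an unadjusted p under 0.05). In nitrogen metabolism, asn1, an asparagine synthetase, was higher by 2.21 (SE 0.20, adjusted p = 4.34e-06), with means of 6.45 at tassel and 7.79 at silking in RIL39 and at most 3.38 in the other lines, and gln5, a glutamine synthetase, lower (-1.16, SE 0.12, adjusted p = 1.59e-05). In sugar metabolism, ivr2 was higher by 2.23 (SE 0.20, adjusted p = 4.26e-06) though in only 5 of 8 pairs, sus2 was lower (-1.26, SE 0.32), a call lost without the 2 RIL39 arrays of lowest 5′ signal (adjusted p = 0.0814), and the branching enzyme sbe1 was higher (0.86, SE 0.15). The ivr2 difference came from silking, where the class was at 6.86 to 7.71 and the favorable lines were at the floor (1.88 to 2.68). At tassel the class was at 11.57 to 13.07 and the favorable lines at 12.43 to 13.12. The silking level was not particular to the class, since RIL118 was at 6.87 and 7.55. With the line as a random block gln5 (adjusted p = 0.0154) and ivr2 (0.00156) still passed, and the other called genes named here did not. Of 6 enzymes matched as C4 and Calvin cycle, 4 were higher (4 adjusted over the list alone): the PEP carboxylase pep1 by 2.76 (SE 0.66, adjusted p = 0.011), pdk1 by 1.19 (SE 0.38, adjusted p = 0.0467), pdlk1 by 0.70 (SE 0.15), which is not a known C4 enzyme, and rbcs1 by 0.43, named after its value was seen. The pep1 call was lost without the 2 RIL39 arrays of lowest 5′ signal, and the pdk1 call held only when the array left out was RIL54 tassel replicate 1, RIL71 tassel replicate 1, RIL118 tassel replicate 1 or 2, or RIL54 silking replicate 1. The pdk1 call was also lost with the replicate block (adjusted p = 0.0594), without a filter (0.0908), with the 5′ to 3′ covariate (0.0912) and without the 2 RIL39 arrays (0.142), and at 2 of its other probe sets pdk1 was not called (0.0972 and 0.904). The rbcs1 call was lost without a filter (0.0644), with the RNA covariate (0.0722), with the 5′ to 3′ covariate (0.0907) and without the 2 RIL39 arrays (0.135). It held only when the array left out was RIL54 or RIL71 tassel replicate 1, RIL54 silking replicate 1, or any of RIL118. A second probe set of asn1 (-0.23, adjusted p = 0.795) and of pdlk1 (0.18, adjusted p = 0.315) was not called. The mean of the C4 and Calvin cycle list was highest in RIL39 (10.53 at tassel and 11.37 at silking), while RIL71 (9.65 and 9.83) lay close to RIL99 (9.40 and 10.08) and RIL54 was at 8.95 and 9.29. Of 8 heat shock proteins 3 were lower (4 adjusted over the list alone): hsp18f at -0.80, hsp70-5 at -0.39 and hsp70-4 at -0.35. The direction held in 7 of 8 pairs for PER42, EXPA5, xet1, asn1, pep1, pdk1 and rbcs1, in 6 of 8 for myb42 and pdlk1, and in 5 of 8 for hsp18f. The 8 photosystem genes gave 0 calls (limma; 6 at an unadjusted p under 0.05, and 4 higher adjusted over the list alone). Camera called 0 of 14 lists, the smallest adjusted p being 0.0524 for photosystem and for C4 genes, and 0.0536 for heat shock; at an unadjusted p under 0.05 these 3 passed, and fry called 1. Each was at adjusted p = 0.877 with an estimated correlation. The 5′ minus 3′ control signal differed by -0.59 (permutation p = 0.214, two-sided), and with the replicate block 1899 probe sets were called.

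The bin 9.02 comparison set RIL118, the only line with the unfavorable allele there, against RIL99 and RIL54. pr5, a thaumatin-like pathogenesis-related protein (gene 542720, chromosome 1), was at 10.14 ± 1.49 in RIL118 (SD, n = 4) and 2.78 ± 0.27 in the favorable lines (n = 8), a difference of 7.37 (SE 0.46), adjusted p = 1.79e-07. bx1 was higher by 4.88 (SE 0.64, adjusted p = 0.000201). The linker histone gene his1 (gene 542385, chromosome 5) was higher by 3.76 (SE 0.11), the pyruvate decarboxylase pdc2 (gene 542651, chromosome 8) by 3.50 (SE 0.24), PEAMT, a phosphoethanolamine methyltransferase (gene 542178), by 3.15 (SE 0.24) and SE1A (gene 732796, chromosome 1) by 2.66 (SE 0.22). The ribosomal protein gene rpl30 (gene 541668, chromosome 8) was lower (-3.15, SE 0.10), as were HIT2 (-2.56, SE 0.39), the expansin expB4 (gene 541909, chromosome 7; -2.10, SE 0.43), oy1, a magnesium chelatase subunit of chlorophyll synthesis (gene 732841, chromosome 10; -2.06, SE 0.43), the light-harvesting protein Lhcb5-2 (gene 542320, chromosome 4; -1.86, SE 0.44) and IPP (gene 541666, chromosome 2; -1.85, SE 0.30). These differed the same way in 4 of 4 pairs of lines at a stage, as the rule that chose them required. The favorable lines themselves differed for his1 (mean 6.29 ± 2.97) and rpl30 (5.26 ± 3.36). The his1 difference rests mostly on RIL54 (3.55), since RIL99 (9.03) was nearer to RIL118 (10.05). Other his1 probe sets gave 1.41 (SE 0.27, adjusted p = 0.00307) and no call (adjusted p = 0.987), and those of IPP were not called (0.154 and 0.215). The rpl30 difference rests on RIL99 (8.38), since RIL118 (2.11) and RIL54 (2.13) were both at the floor. In all, 2279 probe sets were called, 1295 higher and 984 lower, and 1625 differed the same way in all 4 pairs. The Lhcb5-2 call was lost without RIL118 tassel replicate 1 (adjusted p = 0.0707) or silking replicate 1 (adjusted p = 0.0593). The bin 9.02 line difference was called for 1301 probe sets without RIL118 tassel replicate 1 and for 1378 without RIL118 silking replicate 2, and with the replicate block for 2105.

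Of 8 photosystem genes 4 were lower in RIL118 and 4 were not called (7 adjusted over the list alone, 5 after centring), with lhcb5 at -0.95 (SE 0.26), psah1 at -0.78 (SE 0.21) and Cab-m7 at -0.49 (SE 0.14, adjusted p = 0.0259). Both the lhcb5 and the psah1 call were lost without RIL118 tassel replicate 1 (adjusted p = 0.119 and 0.135), without RIL118 silking replicate 1 (0.0975 and 0.0966), and with the 5′ to 3′ covariate (0.0554 and 0.0731). The Cab-m7 call was lost under the same 3 changes (adjusted p = 0.145, 0.124 and 0.0722), in a fit of only the groups compared (0.0501) and without the 2 RIL39 arrays of lowest 5′ signal (0.0506). The mean of the list was 11.98 ± 0.52 at tassel and 11.60 ± 0.44 at silking in RIL118 (SD, n = 2), against 12.20 to 13.13 in the other groups. Of 12 ribosomal proteins 3 were lower (5 adjusted over the list alone, 4 called after centring): rpl30, rpl29 (-0.54) and RPL10 (-0.24). The mean of the list in RIL118 (10.25 at tassel and 10.59 at silking) was close to that in RIL71 (10.37 and 10.63), the other groups being at 10.49 to 11.38. These means depend in part on rpl30, which was at 8.38 in RIL99 and 8.12 in RIL39. It was at the floor in RIL54 (2.13), RIL71 (2.13) and RIL118 (2.11). Over the list's genes the mean difference of RIL118 from the favorable lines was -0.44 and the median -0.20. The list was not tested without rpl30. The rpl29 call was lost without RIL118 tassel replicate 1 (adjusted p = 0.145), RIL118 silking replicate 1 (0.0997), RIL99 tassel replicate 2 (0.0516) or RIL99 silking replicate 1 (0.056), with the 5′ to 3′ covariate (0.0659) and in a fit of only the groups compared (0.0694). That of RPL10 was lost after quantile normalization (adjusted p = 0.0615), in the fit of only the groups compared (0.0828), without the 2 RIL39 arrays (0.054), and without RIL118 tassel replicate 1 (0.101), RIL99 silking replicate 2 (0.0556) or RIL118 silking replicate 2 (0.11). Photosystem and ribosomal lists were each at adjusted p = 0.00574 in the preset test and adjusted p = 0.712 with an estimated correlation. Of 5 pathogenesis-related genes 3 were higher (3 adjusted over the list alone; list adjusted p = 0.161): pr5, prp4 by 2.46 (SE 0.67) and the chitinase chn1 by 1.27 (SE 0.30). The prp4 call was lost without RIL118 tassel replicate 2 (adjusted p = 0.0785) or silking replicate 2 (0.059), in the fit of only the groups compared (0.0771) and with the 5′ to 3′ covariate (0.0509), and that of chn1 without RIL118 silking replicate 2 (0.062). Of 22 aquaporins 5 were higher (1 lower after centring), among them tip1 (1.25, SE 0.21), and of 8 cell cycle genes 3 were higher and 1 lower (3 and 1 adjusted over the list alone; list adjusted p = 0.667). The lower one was pcna1 (-1.20, SE 0.21). The higher ones were cycD2 (0.65, SE 0.15) and kin15 and krp1, which the gene table also places in a kinesin series. krp1 was named after its value was seen, and its call was lost without a filter (adjusted p = 0.0515), in the fit of only the groups compared (0.099), with the 5′ to 3′ covariate (0.0893), without the 2 RIL39 arrays (0.0626), and without any 1 of RIL99 or RIL118 tassel replicate 1, RIL99 tassel replicate 2, or RIL99, RIL54 or RIL118 silking replicate 2 (0.0537 to 0.184). The direction held in 3 of 4 pairs for tip1, cycD2, kin15 and myb42. myb42 was lower (-1.39, SE 0.21, adjusted p = 0.000663) and bk2 higher (1.45, SE 0.33, adjusted p = 0.00937), a call lost without RIL118 silking replicate 1 (adjusted p = 0.0518). None of the monolignol genes passed (limma; 1 at an unadjusted p under 0.05, 0 of 3 adjusted over the list alone): ccr2 was at -0.40 (SE 0.64, adjusted p = 0.69), BM1 at 0.19 (SE 0.08, adjusted p = 0.119) and cncr1 at 0.19 (SE 0.13, adjusted p = 0.322). Nor did pal3 (0.14, SE 0.09, adjusted p = 0.311) and LOC542166 (0.03, SE 0.25, adjusted p = 0.948; 0 of 2 at an unadjusted p under 0.05). Of 2 class III peroxidases 1 was called higher, and so was xet1 (0.69). The laccase LAC1 (0.69) was not called over all probe sets and passed only over its own list of 1 gene. Of 4 meristem regulators 2 were called higher (3 adjusted over the list alone), and knox7 was higher by 0.50 (SE 0.11). The 5′ minus 3′ control signal differed by -0.79 (permutation p = 0.0935, two-sided).

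The differences between lines of the same class give the background for both locus comparisons. In RIL54 rpl30 was at 2.13 ± 0.02 against 8.38 ± 0.58 in RIL99 (SD, n = 4 each), a difference of -6.25 (SE 0.11, adjusted p = 6.2e-13), and his1 differed by -5.49 (SE 0.12). b3gat3 was lower in RIL54 as well (-2.91, SE 0.12). In RIL71 against RIL39, rpl30 differed by -5.98 (SE 0.11, adjusted p = 5.69e-13), tbp1, a TATA-binding protein (gene 542240, chromosome 1), by -6.61 (SE 0.15) and his1 by -5.00 (SE 0.12). The F test among all 5 lines called 4852 probe sets, with rpl30, his1 and tbp1 at the smallest p, and the replicate block gave 4588. RIL54 minus RIL99 gave 1761 calls (881 higher, 880 lower), and RIL71 minus RIL39 gave 1834 (893 higher, 941 lower), with 1618 and 1673 under the replicate block. RIL54 minus RIL99 fell to 1105 without RIL99 silking replicate 1 and to 1150 without RIL99 silking replicate 2. RIL71 minus RIL39 fell to 1030 without RIL39 tassel replicate 2 and to 1139 without RIL39 silking replicate 2. Other groupings of the same lines were counted beside the loci. RIL54 and RIL71 against RIL99 and RIL39 gave 2241 and RIL54 and RIL39 against RIL99 and RIL71 gave 1591, beside 2023 for the bin 6.06 classes. RIL99 against RIL54 and RIL118 gave 2112 and RIL54 against RIL99 and RIL118 gave 1980, beside 2279 for RIL118 against RIL99 and RIL54.

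**Figure D3:**
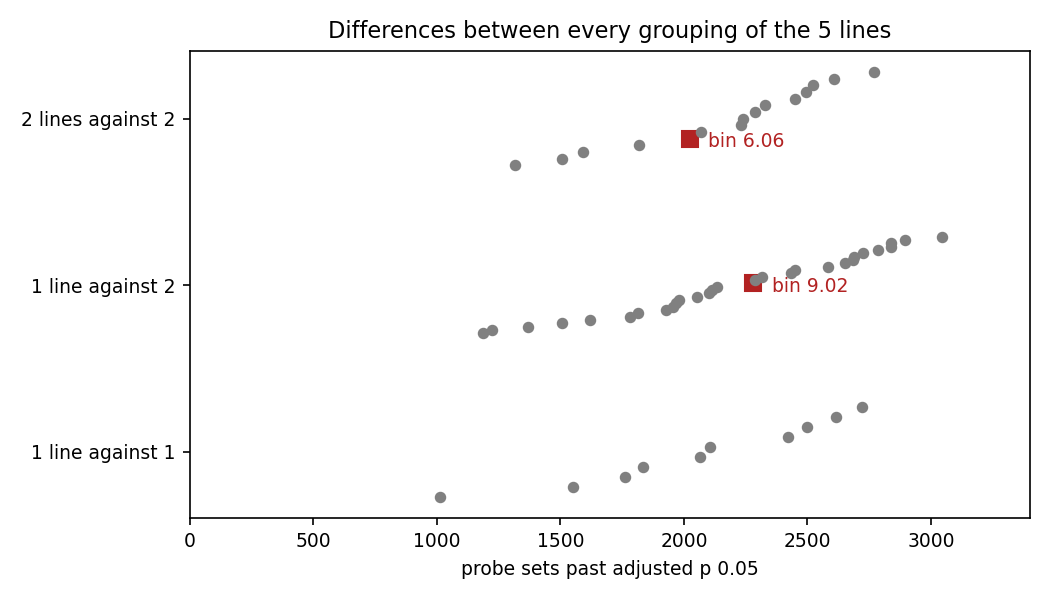
Number of called probe sets for every grouping of the 5 lines as 1 against 1, 1 against 2 and 2 against 2, with red squares for the bin 6.06 (2023) and bin 9.02 (2279) comparisons. Groupings of 2 lines against 2 ran from 1317 to 2771, so the bin 6.06 comparison lies inside the range of groupings that ignore the locus.

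Whether calls gathered on the chromosome of the locus was asked for the probe sets with a known chromosome. On chromosome 6, 14 of 95 probe sets (14.7%) were called in the bin 6.06 comparison, against 16.9% elsewhere (odds ratio 0.85, Fisher's exact p = 0.665). On chromosome 9, 11 of 68 (16.2%) were called in the bin 9.02 comparison, against 20.8% elsewhere (odds ratio 0.734, exact p = 0.436). Chromosome 4, which holds bx1, bx6, acco20, HIT2 and GP, had more calls in both. There 29 of 105 (27.6%) were called in the bin 6.06 comparison against 15.3% elsewhere (odds ratio 2.11, adjusted exact p = 0.0314 over 10 chromosomes), and 37 of 105 (35.2%) in the bin 9.02 comparison against 18.6% (odds ratio 2.38, adjusted exact p = 0.00167). The odds ratio of chromosome 4 was 1.27 for RIL54 minus RIL99 and 1.08 for RIL71 minus RIL39 (exact p = 0.386 and 0.779). The called sets of the 2 locus comparisons shared 749 probe sets, where 418 would be shared if they were independent, and both use the arrays of RIL99 and RIL54. The excess was not particular to the loci. RIL54 minus RIL99 and RIL71 minus RIL39, which have no array in common, shared 541 where 293 would be shared.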

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

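The grouping of the 4 lines without regard to the bin and the covariate for RNA quality were tests chosen after the results were seen. The results below came up because the stage change differed between lines or classes by a test of the interaction itself. The stage by line interaction was called for 679 probe sets, that of the bin 6.06 class and stage for 89, and that of RIL118 and stage for 865. By gene, the log2 interaction with the bin 6.06 class was 5.82 for ivr2, 4.37 for hsp22 and 2.46 for b3gat3. For RIL118 it was 6.48 for ivr2, 7.69 for hsp22 and 2.47 for b3gat3. The class value of hsp22 rests on RIL39, where the stage change was 1.03 against -5.74 in RIL71 and -4.82 in RIL54, and its call was lost without the 2 RIL39 arrays of lowest 5′ signal. The values of b3gat3 rest on RIL99, the only line in which it fell. The silking values of ivr2 in RIL99 and RIL54 lay at the floor (1.88 to 2.68), and those of hsp22 in RIL99 were low (3.36 and 3.37). This limits the size of the interactions of both genes that can be read.

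The stage response was weakest in RIL118: over the probe sets called in the other lines, the mean slope of its stage changes on theirs was 0.56, against 0.80 in RIL39, 0.96 in RIL71, 1.07 in RIL54 and 1.16 in RIL99. The spread between the RIL118 tassel arrays cannot be excluded as the cause. The highest slope of its 4 pairings of single arrays was 0.708, below the lowest pairing of any other line (0.758). Each line was set against the mean of the other lines, however. The reference of every other line thus includes the weak RIL118 response and that of RIL118 does not. The slopes are not on 1 scale, so this narrow margin cannot decide. RNA quality stays open too, although with the 5′ to 3′ covariate RIL118 had 1653 calls and the next line 3589. The 5′ minus 3′ signal of RIL118 was -4.62 and -3.45 at tassel and -3.53 and -4.75 at silking. With so little difference between its stages, the covariate could hardly move its stage change. Signal damped at both stages was not tested. A candidate explanation that stays open is that the RIL118 plants were further along when the tassel emerged: its tassel arrays lay at 0.22 on an axis from tassel (0) to silking (1) and its silking arrays at 0.781, both short of the bounds set for it, though the former was above the bound that would have excluded it, and RIL39 tassel arrays lay at 0.219. Line and allele cannot be told apart here, as RIL118 is the only line with its pattern, and an effect of the allele was not tested.

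Regrouping single arrays tested whether chance among arrays can be excluded. Only 1 of 100 splits, the real one, was as large for the stage effect (7466 against a highest other of 6657), for the line differences (4852 against 258), for the bin 6.06 comparison (2023 against 294) and for the bin 9.02 comparison (2279 against 1456). The splits for the last 3 of these break the lines apart, so they exclude chance among arrays and do not set the loci against other differences between lines; groupings of 2 intact lines against 2 gave 1317 to 2771 calls. For the interactions chance cannot be excluded by this count: 7 of 100 splits were as large for stage by line (679 against a highest other of 6001), 7 for the bin 6.06 class by stage (89 against 3320) and 10 for RIL118 by stage (865 against 5630). In each of the 3, 6 of the splits as large had the stage labels of a whole line exchanged. Such an exchange was common among all the splits, with 62, 56 and 37 in that order. Without the exchanged splits the real split stood alone for the first 2, but for RIL118 by stage 3 further splits were as large. The splits then left beside the real one mix the stages within a line. That puts the stage effect into the spread and lowers their counts, so this does not exclude chance for any of the 3 interactions. The 18 splits of 2 lines are too few for a share under 0.05, with 1 as large each: RIL54 minus RIL99 gave 1761 against a highest other of 343, and RIL71 minus RIL39 gave 1834 against 108. When whole lines were regrouped, 2 of the 3 ways to pair RIL99, RIL54, RIL39 and RIL71, the bin 6.06 pairing included, gave at least its 2023 calls, the highest other being 2241, and with the line as a random block 174 calls were left, so the number of calls does not set the locus apart from other differences between lines.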

How the results depend on the processing

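The RNA quality covariate, the fits without RIL118 and without the 2 RIL39 arrays of lowest 5′ signal, and the lists without unintended members were added after the data were seen, as were some of the genes. For the 205 named genes, 3734 of 4100 values with an array left out kept their direction and side of the threshold, 358 lost the call, 4 gained it and 4 reversed; under other settings 2028 of 2212 kept them, 179 lost the call, 4 gained it and 1 reversed. The reversed values were never called: LOC542166 in the bin 9.02 comparison was -0.000388 after centring, -0.156 without RIL54 silking replicate 1 and -0.178 without RIL118 silking replicate 1 (-0.178 to 0.235 over all arrays left out); ccr2 in the bin 9.02 comparison was 0.464 without RIL118 tassel replicate 2 (-1.27 to 0.464); and pal3 in the bin 6.06 comparison was 0.0212 without RIL54 silking replicate 2 (-0.102 to 0.0212). Of 199 counts and odds ratios under other settings, 157 stayed within 1.5 times or kept their call. With 1 probe set per gene only 808 were tested, and the counts fell to 508 for stage, 353, 301, 215, 248 and 69 within RIL99, RIL54, RIL39, RIL71 and RIL118, 35 for stage by line, 366 for line, 143 for bin 6.06, 5 for bin 6.06 by stage, 172 for bin 9.02, 73 for bin 9.02 by stage, 129 for RIL54 minus RIL99 and 130 for RIL71 minus RIL39; fewer tests are part of the cause. The stricter filter gave 22 for bin 6.06 by stage. A fit of only the groups compared, which has fewer arrays, gave 365, 680 and 15 within RIL54, RIL71 and RIL118, 138 for bin 6.06 by stage and 242 for bin 9.02 by stage. The RNA covariate gave 2055 within RIL54, 788 within RIL118 and 423 for bin 9.02 by stage. The line as a random block gave 174 for bin 6.06, since it sets the class in part against the spread between lines. It does so with 1 correlation (0.303) for all probe sets. The 5′ to 3′ covariate gave 1047 for RIL71 minus RIL39, and leaving out RIL118 gave 138 for bin 6.06 by stage. Without the 2 RIL39 arrays the counts were 315 within RIL39, 713 within RIL118, 181 for stage by line, 3165 for line, 1242 for bin 6.06, 38 for bin 6.06 by stage, 302 for bin 9.02 by stage and 682 for RIL71 minus RIL39. Leaving out each array in turn gave 7051 to 7600 for stage, 3239 to 5213 within RIL99, 2043 to 4272 within RIL54, 1233 to 3266 within RIL39, 1566 to 3858 within RIL71, 180 to 1497 within RIL118, 320 to 1195 for stage by line, 3706 to 5454 for line, 1507 to 2281 for bin 6.06, 55 to 206 for bin 6.06 by stage, 1301 to 2925 for bin 9.02, 172 to 1585 for bin 9.02 by stage, 1105 to 1958 for RIL54 minus RIL99 and 1030 to 2025 for RIL71 minus RIL39. Of the 14 lists tested for stage, preset camera called 4, camera with an estimated correlation 0 and fry 10; for bin 9.02 the numbers were 2, 0 and 5; for bin 6.06, where preset camera called 0, fry called 1 and the test without a filter 3. Counting only calls that change by at least 1 on the log2 scale gave chromosome 9 odds ratios of 2.66 for RIL54 minus RIL99 and 2.55 for RIL71 minus RIL39 (exact p = 0.019 and 0.0145, not adjusted over chromosomes). Where no cause is given here, the cause was not tested. Signal near the floor of the array values limits the size of the changes of the dimmest genes.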

Other observations

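The decision bounds of the tests of a linked stretch and of single probe sets were changed after their values were seen, as described below; the tests themselves were chosen before. The genes of the first paragraphs were chosen after their values were seen. bx1, of benzoxazinoid synthesis, was at 6.26 ± 0.80 at tassel and 6.29 ± 0.86 at silking in RIL99, and at 7.12 ± 3.16 and 8.94 ± 0.63 in RIL54 (SD, n = 2). The RIL54 tassel arrays were at 9.35 and 4.89, the former above a tassel array of RIL71 (9.22). It was at 12.03 ± 0.07 and 10.51 ± 0.38 in RIL39, at 9.42 ± 0.28 and 9.23 ± 0.58 in RIL71, and at 11.98 ± 0.21 and 12.09 ± 1.11 in RIL118. bx6 of the same pathway was at means of 7.44 and 7.41 in RIL99, 9.90 and 7.83 in RIL54, 11.81 and 11.15 in RIL39, 10.34 and 9.93 in RIL71, and 9.32 and 9.67 in RIL118.

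Some genes of histone deacetylases and nucleosome assembly were higher at silking. nfa101 rose by 1.71 (SE 0.15, adjusted p = 1.15e-06), nfa103 by 1.34 (SE 0.11, adjusted p = 8.47e-07), hda110 by 1.08 (SE 0.11, adjusted p = 4.68e-06) and HDA108 by 0.70 (SE 0.07, adjusted p = 2.72e-06), while hda101 was at 0.09 (SE 0.06, adjusted p = 0.173), and at 0.17 (adjusted p = 0.0394) without RIL118. Glutathione transferases went both ways, with gst6 at -2.29 (SE 0.30), gst14 at -2.33 (SE 0.33) and gst1 at -1.25 (SE 0.20), against GST39 at 1.57 (SE 0.23) and gst17 at 0.94 (SE 0.12), all 5 called. These groups were not among the lists fixed in advance, and no list test was run on them.

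The larger share of calls on chromosome 4 was weighed against 3 explanations. Several probe sets of the same genes are argued against, since with 1 probe set per gene the smaller of the odds ratios was 2.16. Noise of the arrays shared by both comparisons stays open: the bin 6.06 class and RIL118 gave odds ratios of 2.02 and 2.14 against RIL99 but 1.08 and 1.53 against RIL54, while RIL118 against RIL39 and RIL71, which uses no favorable array, gave 1.85 (exact p = 0.00504). A linked stretch of chromosome 4 cannot be told apart from scattered genes: called genes lay next to each other 9 times in the bin 6.06 comparison (median of shuffles 7) and 11 times in the bin 9.02 comparison (median 12, with 8 to 15 between the 5% and 95% points of the shuffles), with a larger permutation p of 0.712, one-sided. The bound first set, a count at or below the median, would have excluded a stretch on the latter value, and it was widened because 11 lies within that range.

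Some genes were at or near the floor in some lines and well expressed in others, like rpl30, his1 and tbp1: 959 probe sets had line means that spanned 2 or more on the log2 scale, 291 of them with a line mean under 3. Sequence differences under single probe sets could be the cause, and they stay open: over 12 genes with another probe set the median slope of the partner was 0.873, with a bootstrap interval of 0.098 to 0.969, 5 genes being under 0.25 and 7 at 0.5 or more. The bound first set on the median alone was replaced by one on this interval after the value was seen, since the genes split. Probe sets that bind related transcripts also stay open, with an odds ratio of 1.15 (95% interval 0.869 to 1.51), and a true absence of the transcript in a line was not tested.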
